A study of Mus musculus with 24 samples.

How the data were processed

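Gene expression was measured in 24 mouse samples on single-colour expression arrays, 1 array per sample. The mice were of the outbred strain ICR-CD1. The samples fell into 6 groups of 4: material named whole embryo at embryonic day 7.5 (ED7.5) and 14.5 (ED14.5), and liver at postnatal day 7.5 (PD7.5), each from grandoffspring of control or of obese (SL) grandfathers. What SL abbreviates is not given in the sources used here. Per the labels' protocols, samples were snap-frozen after euthanasia, total RNA was extracted with Trizol, and biotin-labelled cRNA was prepared from 6 µg of total RNA by an Affymetrix protocol.

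The deposited values are probe set summaries on a log2 scale. Per the submitters' processing notes, the authors made them with RMA, a method of background correction, quantile normalization and probe summary, in the oligo package. The version, and whether all 24 arrays were run together, are not given in the sources used here. The log2 scale was inferred from the method and from the range of the values, and the values are not centred per gene. A joint run was inferred from 193 exact values that recur in at least 3 arrays, 179 of them in more than 1 age. No further normalization was applied. All differences below are therefore differences of log2 values, and folds are powers of 2 of them.

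The values covered 29129 probe sets, of which 6923 were control features and 22206 were not. Of the latter, 19572 named exactly 1 gene and 2634 named no gene in the annotation used here. Where a gene had several probe sets, which held for 55 genes, the brightest over the 24 arrays was used. This left 19505 genes, and all were tested. The probe sets without a gene name were tested apart from these. T, H19, Hbb-bt, Hba-a1, Neurod1, Srebf1 and Xist had no named probe set and were not analysed here. The background of an array was taken as the value below which 75% of its 5222 intron control probes lay. A fold against a group whose arrays all lay at or below background was computed against that background and is given as a lower bound. The number of arrays limits the precision, with a median standard error per gene of 0.144, 0.143 and 0.187 in log2 for the ED7.5, ED14.5 and liver comparisons of SL with control, and of 0.149 for the comparison of the ages.

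Within each age the 4 SL arrays were compared with the 4 control arrays, and the ED14.5 control arrays were compared with the ED7.5 control arrays. Each used a linear model with moderated variances in limma 3.58.1 under R 4.3.3, with files read by the data.table package (1.17.8). P-values were two-sided and adjusted by the Benjamini-Hochberg method over the genes of a comparison, with a threshold of 0.05. Differences of the SL effect between ages were tested as interaction terms in a fit of all 24 arrays. Gene lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists of a comparison (31 at ED7.5, 31 at ED14.5, 33 in the liver and 24 between the ages). Camera with an estimated correlation, limma's fry and an exact two-sided permutation of the array means of each list were run beside it. The 70 regroupings of 8 arrays allow no exact permutation p below 0.0286. Where a count of list members is said to be adjusted over the list alone, the adjustment covered the measured members of that list. Differences of the SL effect between ages were tested only for lists that camera called in an SL comparison, and adjusted over these lists alone. P-values measure only the spread between samples, since the labels do not say whether the samples of a group came from separate litters or grandfathers.

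The comparisons, the 55 gene lists, the rule for naming genes and the alternatives were chosen before the data were examined, except where stated. For each SL comparison the rule took up to 10 genes per direction with the largest change among those past the threshold whose groups did not overlap. Where fewer than 5 genes passed in a direction, it took the 5 with the smallest p among genes whose groups did not overlap. It then took the 4 members with the smallest p of each list past its threshold, and every list member past the threshold adjusted over its list alone, up to 15 with the largest change in all. To these it added 35 anchor genes of the tissues whatever their values. The comparison of the ages named 5 genes per direction and 2 members per list. Symbols of predicted or unnamed genes were passed over. Lists of heat shock, epithelium and clock genes were written later, each before its test. A few further genes are named below with a statement that they were chosen after their values were seen.

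The alternatives were a variance model with an intensity trend and a robust prior, array weights, a fit of all 24 arrays, the replicate number as a block, leaving out the dimmest 33% of genes, quantile normalization within the comparison, other uses of several probe sets, a score of Y-linked genes as a covariate in place of a sex score with Xist, an adjusted p under 0.10, a minimum change of 0.5, and leaving out each array in turn. Added after seeing the data were the separation of exon from intron control probes as a covariate, the mean of the epiblast genes as a covariate at ED7.5, and the liver lists without control replicate 3 and SL replicate 1. The area under the curve that separates 1324 exon control probes from the intron control probes served as a measure of array quality. Neighbours of a gene were taken from a mouse RefSeq gene table. The model was tested on simulated data of the same size and spread, with independent noise per gene. In each comparison 200 genes were changed, by 0.5, 1, 2 or 4 in log2. With 4 arrays against 4, it called 56%, 70%, 46% and 74% of genes changed by 1 in the ED7.5, ED14.5, liver and age comparisons. It called at least 94% of those changed by 2. Where fewer genes change, the adjusted threshold is harder to reach. These shares are therefore likely too high for the SL comparisons, where few genes passed.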

Results

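Expression was profiled in 24 samples from grandoffspring of control or obese (SL) male mice, with 4 arrays per group at ED7.5, ED14.5 and PD7.5. Each array measured 19505 named genes. Between 48.3% and 64.1% of these lay above the background of their array. Median log2 values per array ran from 5.66 to 6.02 in the ED7.5 control group, from 5.74 to 5.81 in ED7.5 SL, from 5.81 to 5.96 in ED14.5 control, from 5.82 to 5.87 in ED14.5 SL, from 5.80 to 5.90 in liver control and from 5.87 to 5.94 in liver SL. Arrays of the same group correlated across genes with a median Pearson r of 0.989, and arrays of the same age from the other arm with 0.988. Between ages the median r was 0.854 for ED7.5 with ED14.5, 0.914 for ED14.5 with liver and 0.815 for ED7.5 with liver. Genes are not independent replicates.

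The markers of the tissues showed which transcripts each kind of sample held. On the ED7.5 control arrays the genes of the decidua, the maternal tissue around the implanted embryo, had a mean percentile of 98.1 among named genes, and 19 of their 21 members lay above background on every array of the group. Prl8a2, a prolactin family hormone of the decidua, averaged 13.32 ± 0.0773 in log2 (SD, n = 4). The visceral endoderm genes stood at percentile 46.6 and the genes of the epiblast, from which the embryo proper forms, at 33.2, with 1 of 15 above background on every array. Pou5f1, a transcription factor of the epiblast, averaged 5.09 ± 1.01 and was above background on 2 of 4 control arrays. The SL arrays of this age had a decidua percentile of 98.4.

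On the ED14.5 control arrays the hepatocyte genes had a mean percentile of 99.6 and those of definitive erythroid cells 99, while the genes of neurons, skeletal muscle and cartilage stood at 22.1, 33.4 and 35.9. Alb averaged 13.51 ± 0.0204 and Afp 13.11 ± 0.0221 (SD, n = 4), against 13.80 ± 0.0484 and 12.97 ± 0.074 in the control liver at PD7.5. Myog, a regulator of muscle differentiation, and Col2a1, the main collagen of cartilage, were above background on 0 of the 4 ED14.5 control arrays. Cyp2e1, a cytochrome of the liver after birth, averaged 3.46 at ED14.5 and 12.92 in the PD7.5 liver, and the embryonic globin Hbb-y 12.61 and 3.12. The labels name both kinds of embryo sample whole embryo. The ED14.5 SL arrays held the same order, with percentiles of 99.5 for hepatocytes, 98.8 for erythroid cells and 22.0 for neurons. The plot of marker lists by age shows these levels per array.

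**Figure D1:**
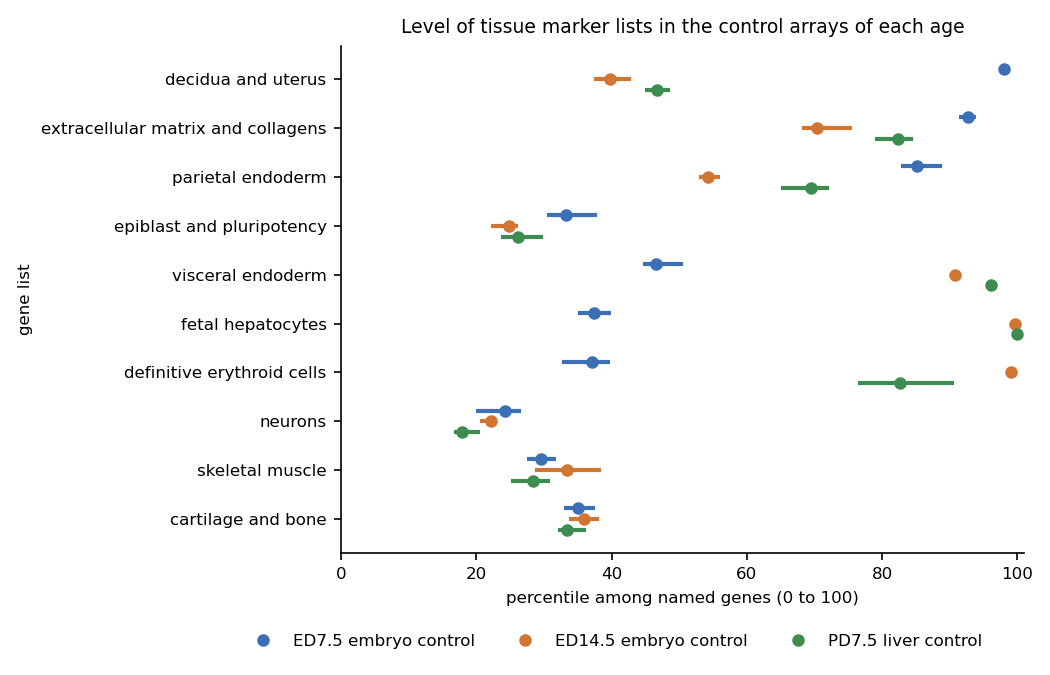
Percentile among named genes (x axis, 0 to 100) of 10 marker lists on the control arrays of each age; the dot is the mean over 4 arrays of the median percentile of the list, and the line runs from the lowest to the highest array. Decidua genes lead at ED7.5 (98.1), and hepatocyte genes at ED14.5 (99.6) and in the PD7.5 liver (99.9).

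The first comparison asked how expression at ED7.5 differed by the grandfather's obesity. Gdpd3, a member of the glycerophosphodiester phosphodiesterase family, rose in the SL samples from 4.70 ± 0.79 to 8.57 ± 0.297 in log2 (SD, n = 4 per group), by 3.88 (SE 0.343, adjusted p = 0.0139). It was above background on 0 of 4 control and 4 of 4 SL arrays, so the rise was at least 7.57-fold. It was the only gene past the threshold in this comparison. An unadjusted p below 0.05 was reached by 1070 genes (547 higher, 523 lower), where 975 are expected by chance. In 594 genes (3.05%) the groups did not overlap, where chance gives 2.86%.

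Genes next in rank at ED7.5, among those whose groups did not overlap, did not pass. The adhesion receptor Adgrg7 was 1.39 higher in SL samples (adjusted p = 0.358), and Mt4, a metallothionein of stratified epithelia, 1.04 higher (adjusted p = 0.634). Values for Mc5r and F11 were 1.42 and 0.70 higher, with both groups below background. Scnn1g, a subunit of the epithelial sodium channel, differed by −0.95 (adjusted p = 0.401), Sat2 by −0.81 (adjusted p = 0.57), the potassium channel Kcnj12 by −1.23, the growth factor Btc by −0.77 (above background on 1 of 8 arrays), and the epithelial splicing factor Esrp2 by −0.63 (adjusted p = 0.634 for these 3). Among the anchor genes of the early embryo, Pou5f1 differed by −0.11, Eomes by 0.07, Mesp1 by 0.26, Sox17 by 0.15, Cdx2 by 0.04, Afp by −0.46, Hbb-bh1 by −0.35 and Igf2 by −0.49 (SE 0.353), and no anchor gene passed. Cdx2, Mesp1 and Hbb-bh1 lay below background on all arrays, and Pou5f1 and Afp on all 4 SL arrays.

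Of 31 gene lists at ED7.5, the ribosomal protein genes rose, by a median of 0.10, with 24 of 26 members above 0 (camera adjusted p = 0.00229). The call was lost with an estimated correlation (adjusted p = 0.842 with an estimated correlation). Single members did not pass the adjustment over the list alone: Rpl27 was 0.30 higher, Rps14 0.27, Rplp0 0.25 and Rplp1 0.20 (adjusted p = 0.612 for each over the list alone). In the visceral endoderm list Amn, a receptor partner of cubilin, rose by 0.45 (SE 0.113, adjusted p = 0.0461 over the list alone), and in the imprinted list Plagl1, a zinc finger regulator of an imprinted network, rose by 0.62 (SE 0.127, adjusted p = 0.019 over the list alone). Both missed the threshold over all genes (adjusted p = 0.725 for Amn and 0.634 for Plagl1). The decidua genes differed by a median of 0.03 (adjusted p = 0.611) and the epiblast genes by −0.11 (adjusted p = 0.391).

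Gdpd3 kept a change of 3.52 to 4.10 when any array was left out, but its adjusted p was 0.0624 without control replicate 1, 0.0964, 0.0682, 0.0787 and 0.0732 without SL replicates 1, 2, 3 and 4 in turn, and 0.05 with the Y score as a covariate. The Y-linked Eif2s3y was above background on 0 of 4 arrays in each group at this age, so the score does not separate the sexes here. The ribosomal protein list had an adjusted p of 0.231 without control replicate 2, the array with the lowest separation of exon from intron control probes (0.867) and the highest background (6.53), and of 0.0552 and 0.144 without SL replicates 2 and 4, and of the 35 splits of the 8 arrays, the real split included, 3 called at least as many genes and 30 at least as many lists.

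The second comparison asked the same at ED14.5, where 10 genes passed, 6 higher and 4 lower in SL embryos. Cirbp, the cold-inducible RNA-binding protein, rose from 8.33 ± 0.117 to 10.12 ± 0.131 in log2 (SD, n = 4 per group), a 3.45-fold rise (1.79, SE 0.106, adjusted p = 0.00054). Angptl4, a secreted inhibitor of lipoprotein lipase and target of PPAR receptors, rose by 0.90 (SE 0.112, adjusted p = 0.0456), and Glo1, which detoxifies methylglyoxal, by 0.70 (SE 0.087, adjusted p = 0.0456). Egr1, an immediate early transcription factor, fell by 1.21 from 8.71 to 7.50 (SE 0.152, adjusted p = 0.0456). Rap1gap, which inactivates the small GTPase Rap1, fell by 1.36 to below background (SE 0.152, adjusted p = 0.0456), at least 1.3-fold lower.

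The other called genes at ED14.5 lay near background. Zc3h6, a zinc finger protein, rose by 1.01 (SE 0.089, adjusted p = 0.00948), at least 1.28-fold, and Septin1, a cytoskeletal GTPase, by 1.12 (SE 0.142, adjusted p = 0.0456). Fbxo44, an F-box protein, rose by 1.57 (SE 0.202, adjusted p = 0.0464) with 1 of 8 arrays above background. Aldh1a7 and Naip6 fell by 1.43 and 0.87 (adjusted p = 0.0456 for both) with all 8 arrays below background. In each of the 10 genes all 4 SL arrays lay on one side of all 4 control arrays, as in the plot of the called genes. Akr1c19, an aldo-keto reductase, differed by −0.83 and did not pass (adjusted p = 0.0596). Across all genes 2223 had an unadjusted p below 0.05 (1090 higher, 1133 lower, 975 expected), and the groups did not overlap in 1556 (7.98%, where chance gives 2.86%).

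**Figure D2:**
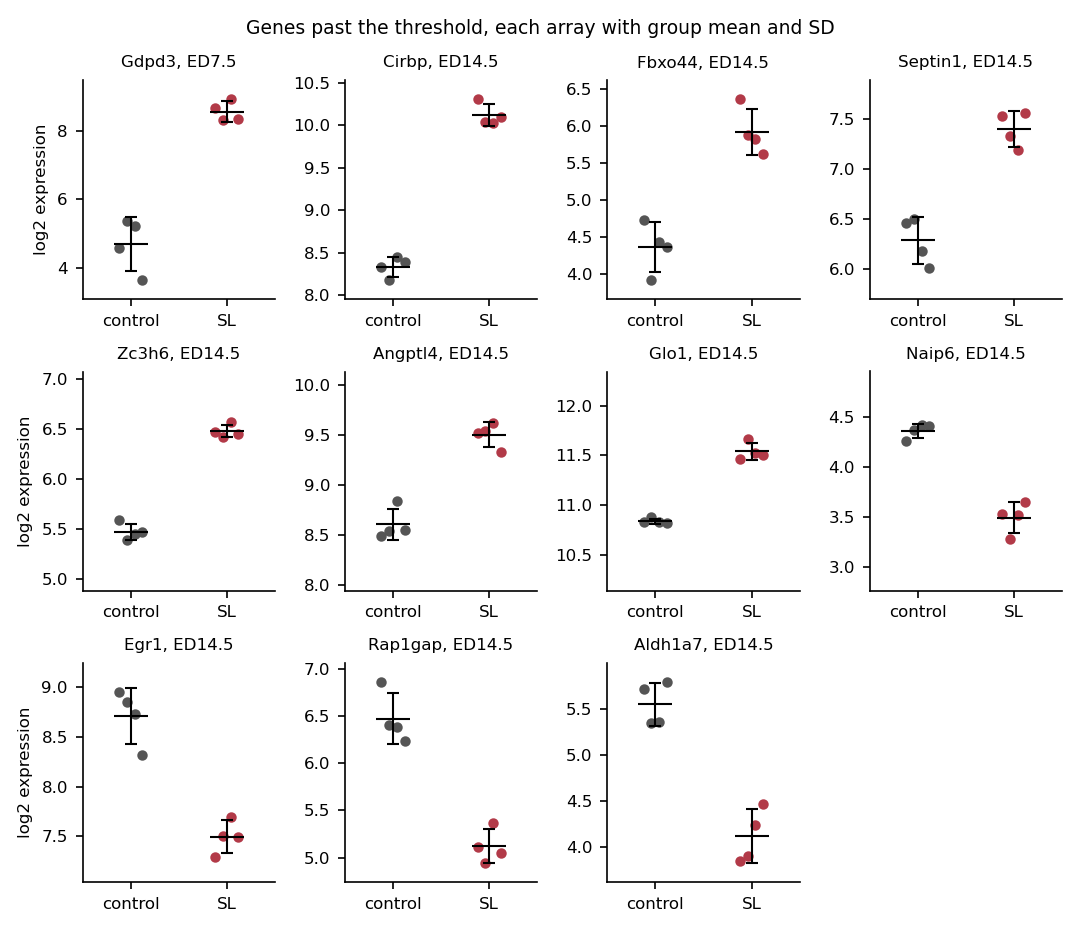
Log2 value (y axis) on each array for the 11 genes past the threshold in a comparison of SL with control, with the group mean ± SD (n = 4). Gdpd3 is shown at ED7.5, where it goes from 4.70 to 8.57, and the other 10 at ED14.5, where Cirbp goes from 8.33 to 10.12 and Egr1 from 8.71 to 7.50.

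Lipid metabolism genes at ED14.5 moved in opposite directions by list. The PPARα targets and genes of fatty acid oxidation rose, by a median of 0.15, with 25 of 29 members above 0 (camera adjusted p = 0.000103, adjusted p = 0.557 with an estimated correlation). Adjusted over the list alone, 4 members rose: Pdk4, which restrains pyruvate oxidation, by 1.21 (SE 0.174, adjusted p = 0.00174), Pex11a, a peroxisomal membrane protein, by 0.73 (at least 1.29-fold, adjusted p = 0.00569), Cpt1a, the entry enzyme of mitochondrial fatty acid oxidation, by 0.64 (SE 0.133, adjusted p = 0.00609), and Ehhadh of the peroxisomal pathway by 0.46 (adjusted p = 0.00569). Cholesterol synthesis genes fell by a median of 0.19, with 18 of 20 members below 0 (camera adjusted p = 1.85e-05, adjusted p = 0.557 with an estimated correlation). Mvd fell by 0.55, Cyp51 by 0.40 and Dhcr7 by 0.40 (adjusted p = 0.0343 for each over the list alone). Fatty acid synthesis genes fell by a median of 0.13, with 15 of 20 below 0 (camera adjusted p = 0.0229, adjusted p = 0.71 with an estimated correlation). Within this list Pnpla3 fell by 0.54 and Gpam by 0.37, while Lpin1, a phosphatidate phosphatase and transcriptional partner of PPARα, rose by 0.59 (adjusted p = 0.035 for each over the list alone). Ehhadh, Mvd, Cyp51, Dhcr7, Pnpla3 and Gpam were chosen after their values were seen.

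The remaining lists called at ED14.5 concern protein folding, redox defence and translation. Unfolded protein response genes fell by a median of 0.20, with 19 of 20 below 0 (camera adjusted p = 1.85e-05, adjusted p = 0.557 with an estimated correlation). Xbp1, a transcription factor of this response, fell by 0.38 and Creld2, a chaperone of the endoplasmic reticulum, by 0.36 (adjusted p = 0.0314 for both over the list alone). The NRF2 and oxidative stress genes rose by a median of 0.08, with 18 of 20 above 0 (camera adjusted p = 0.0338, adjusted p = 0.557 with an estimated correlation), and Gsr, glutathione reductase, rose by 0.45 (adjusted p = 0.025 over the list alone). Xbp1, Creld2 and Gsr were chosen after their values were seen. Ribosomal protein genes rose by a median of 0.07, with 21 of 26 above 0 (camera adjusted p = 0.0395, adjusted p = 0.831 with an estimated correlation). Of the 35 splits of the ED14.5 arrays, 4 called at least 6 lists, the real split included.

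Marker genes of the tissues at ED14.5 did not pass over all genes. Alb differed by −0.02, Afp by −0.06, Dlk1 by −0.03, Igf2 by −0.02, Myog by 0.10 and Col2a1 by 0.07, with an adjusted p of 0.829 to 0.959. Hepatocyte genes as a list had a median difference of −0.02 and a mean of 0.01 (camera adjusted p = 0.874), and definitive erythroid genes a median of −0.10 (adjusted p = 0.273). Adjusted over its list alone, Gap43, a protein of growing axons, rose by 0.71 (adjusted p = 0.00781), Clec4g, a lectin of sinusoidal endothelium, fell by 0.57 (adjusted p = 0.0378), and Igfbp1, a binding protein of IGFs made by hepatocytes, rose by 0.88 (adjusted p = 0.0317). Tnnt2 and Synb passed in the same way, by 0.68 (adjusted p = 0.00429) and −0.997 (adjusted p = 0.00545), with all arrays below background.

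Cirbp kept its call when any array was left out, with adjusted p from 0.00211 to 0.00656, while the number of called genes at ED14.5 dropped to 4, 1, 1 and 4 without control replicates 1, 2, 3 and 4, and to 1, 3, 1 and 5 without SL replicates 1, 2, 3 and 4. The cholesterol, unfolded protein and PPARα lists passed without each of the 8 arrays, while the fatty acid synthesis list had adjusted p of 0.0554, 0.112 and 0.127 without control replicates 3 and 4 and SL replicate 1, the NRF2 list 0.0554 to 0.108 without control replicates 1, 3 and 4 and SL replicates 2 and 3, and the ribosomal list 0.0554 to 0.267 without control replicates 1, 2 and 3 and SL replicates 1 and 2. With the replicate number as a block, the NRF2 and ribosomal lists had camera adjusted p of 0.0735 and 0.0986. With the Y score as a covariate, the fatty acid synthesis, NRF2 and ribosomal lists had 0.0505, 0.0505 and 0.0995.

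The third comparison asked for a difference in the liver at PD7.5. By limma, 0 genes passed, with a smallest adjusted p of 0.509, and 1543 genes had an unadjusted p below 0.05 (836 higher, 707 lower, 975 expected). The groups did not overlap in 864 genes (4.43%, where chance gives 2.86%). Among the genes with the smallest p, values were lower for Irf7, a master regulator of interferon responses (−1.12, SE 0.21), Slc22a28, an organic anion transporter family member (−1.74, SE 0.313, at least 1.95-fold lower), the pro-apoptotic Bid (−0.85), Tbc1d7 (−0.83) and the chemokine Ccl24 (−0.74). Zar1l (0.86, above background on 2 of 8 arrays) and H2al2a (0.70) had higher values, as had Scube2 (1.01), Fbxo43 (1.63) and Morn3 (1.18), which lay below background on all arrays. The adjusted p was 0.509 for all 10, which were picked from genes whose groups did not overlap.

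As lists, liver genes of sterol and fatty acid synthesis fell in SL animals. Cholesterol synthesis fell by a median of 0.27, with 20 of 20 members below 0 (camera adjusted p = 2.78e-08, adjusted p = 0.45 with an estimated correlation). Mvk, mevalonate kinase, differed by −0.81 and Sqle, squalene epoxidase, by −0.80, and both narrowly missed the adjustment over the list alone (adjusted p = 0.0533 and 0.0537). Fatty acid synthesis genes fell by a median of 0.11, with 17 of 20 below 0 (camera adjusted p = 0.0019, adjusted p = 0.45 with an estimated correlation). Thrsp, a regulator of lipogenesis, fell by 1.11 to below background, at least 1.23-fold (SE 0.232, adjusted p = 0.0166 over the list alone), while Pnpla3 and Fasn had differences of −0.63 and −0.51 that did not pass (adjusted p = 0.113 and 0.0684 over the list alone). Unfolded protein response genes fell by a median of 0.14, with 16 of 20 below 0 (camera adjusted p = 0.00216, adjusted p = 0.45 with an estimated correlation). On these arrays the separation of exon from intron control probes was 0.913 in control and 0.902 in SL livers (exact permutation p = 0.0286), and the Y score 6.05 and 6.25 (exact permutation p = 0.0286). The Y-linked Eif2s3y was above background on 4 of 4 arrays in each group. Unequal numbers of male samples therefore do not account for the shift in the score.

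**Figure D3:**
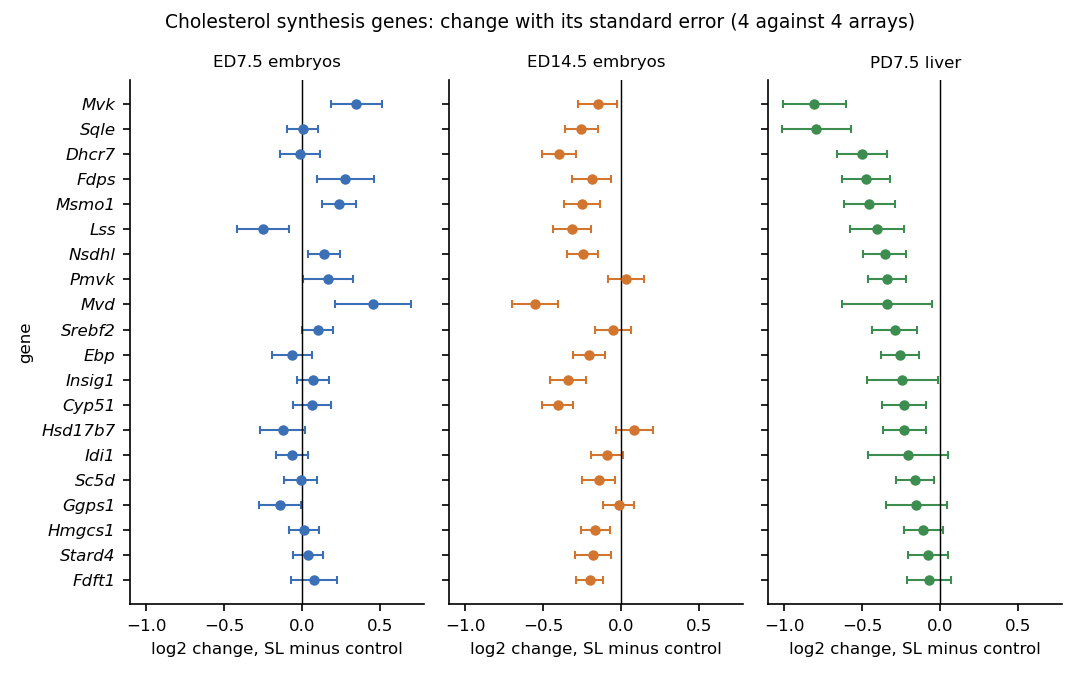
Log2 change of SL against control (x axis) ± SE for the 20 measured genes of cholesterol synthesis, in 1 panel per age (n = 4 per group). At ED14.5, 18 of the 20 lie below 0, and in the liver all 20 do.

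Of the blood and immune cell lists of the liver, those of leukocytes (a median of 0.11, camera adjusted p = 0.211) and lymphocytes (0.01, adjusted p = 0.765) did not pass. Kupffer cell genes fell by a median of 0.21, with 12 of 14 below 0 (camera adjusted p = 0.000689, adjusted p = 0.45 with an estimated correlation). Folr2, a folate receptor of resident macrophages, fell by 0.71 and C1qa, a complement component named after its value was seen, by 0.50 (adjusted p = 0.0261 for both over the list alone). Interferon response genes fell by a median of 0.23, with 16 of 19 below 0 (camera adjusted p = 0.000689, adjusted p = 0.45 with an estimated correlation). Within that list Irf7 passed alone (adjusted p = 0.00708), and Ifit1, Isg15 and Oasl2 had differences of −1.0 (at least 1.44-fold), −0.65 (at least 1.11-fold) and −0.62 that did not. Granulocyte and progenitor genes rose by a median of 0.38, with 13 of 16 above 0 (camera adjusted p = 0.000689, adjusted p = 0.777 with an estimated correlation). Camp, the cathelicidin of neutrophil granules, rose by 0.63 (adjusted p = 0.0397 over the list alone), and Chil3 was 0.70 higher without passing (adjusted p = 0.0789). The granulocyte list did not pass without control replicate 4 (adjusted p = 0.0527).

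Definitive erythroid genes of the liver fell by a median of 0.42, with 15 of 15 below 0 (camera adjusted p = 0.00137, adjusted p = 0.844 with an estimated correlation). The members Trim10, Epb42 and Klf1 had differences of −0.70, −0.66 and −0.54, with adjusted p = 0.424 over the list alone. Cell cycle genes fell by a median of 0.21, with 27 of 28 below 0 (camera adjusted p = 0.000721, adjusted p = 0.844 with an estimated correlation). The percentile of the erythroid list ran from 76.5 to 90.6 on control and from 57.1 to 84.8 on SL arrays. The shift in probe separation and Y score between the liver groups (0.913 against 0.902 and 6.05 against 6.25, exact permutation p = 0.0286 for each) applies to these lists too. Since Eif2s3y was above background on every liver array, the Y score does not stand for a difference in sex here. With the separation as a covariate 6 of the 8 lists stayed called, the interferon and Kupffer lists did not (adjusted p = 0.596 and 0.177) and the pancreas list passed in the reverse direction (adjusted p = 0.0333), and with the Y score as a covariate the interferon list did not (adjusted p = 0.257). Neither measure overlapped between the liver groups (separation 0.906 to 0.920 in control, 0.897 to 0.904 in SL). Array quality and SL therefore cannot be told apart on the liver arrays, and a list that stayed called does not separate them. The erythroid and cell cycle lists had adjusted p of 0.132 and 0.4 without control replicate 2 and of 0.22 and 0.342 without SL replicate 4, and 4 of the 35 splits of the liver arrays called at least 8 lists, the real split included.

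The liver's anchor genes of metabolism did not pass. Among regulators, Ppara differed by −0.01 and Nr1h3, the liver X receptor α, by 0.01. Cpt1a differed by −0.04, Scd1 by −0.01, Cyp7a1, the rate-limiting enzyme of bile acid synthesis, by −0.28, and Fgf21, a fasting hormone, by −1.03 (SE 0.513), with 3 of 4 control and 0 of 4 SL arrays above background, so its size is not exact. The gluconeogenic genes G6pc and Pck1 were 0.39 and 0.34 higher, Igf1 0.03, Igfbp1 0.15, and Afp differed by −0.27. In the glycolysis list Pdk1, which inhibits pyruvate dehydrogenase, rose by 0.60 (SE 0.126, adjusted p = 0.0178 over the list alone).

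Differences of the SL effect between ages were tested directly. Age goes together with the kind of sample here, so a difference between ages cannot be told from a difference between tissues. Between ED14.5 and ED7.5, 15 genes differed (9 higher, 6 lower in the ED14.5 effect, with 1349 at an unadjusted p below 0.05). Cirbp differed by 2.07 (adjusted p = 1.13e-05) and Gdpd3 by −4.23 (adjusted p = 0.000359), a size that is not exact, since Gdpd3 was above background on 1 of 8 ED14.5 arrays and on 0 of 4 control arrays at ED7.5. Between liver and ED14.5, 5 genes differed, all lower in the liver effect, with Cirbp at −1.59 (adjusted p = 0.00115). Between liver and ED7.5 the gene that differed was Gdpd3, at −3.30 (adjusted p = 0.0357) with 1 of 8 liver arrays above background. Of the lists, only those that camera called in an SL comparison were tested, with p adjusted over these alone. For cholesterol synthesis the change was lower at ED14.5 than at ED7.5 by a median of −0.24 (camera adjusted p = 1.06e-05, adjusted p = 0.194 with an estimated correlation), and lower in the liver than at ED7.5 by −0.30 (camera adjusted p = 6.49e-09, adjusted p = 0.122 with an estimated correlation). Liver and ED14.5 did not differ detectably for this list (−0.10, camera adjusted p = 0.0839), which does not show that they share a change. All 20 of its genes were below 0 in the liver, so the 18 below 0 at ED14.5 were below 0 in both, and this overlap adds no evidence.

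Over all 19505 genes the SL changes of different ages correlated no more strongly than those of regrouped arrays. Pearson's r across genes was −0.0123 between ED7.5 and ED14.5, −0.0112 between ED7.5 and liver and 0.038 between ED14.5 and liver, with Spearman's rho of −0.00236, −0.0371 and 0.034. Of 100 random regroupings within ages, 78, 75 and 40 gave an r as large in size, and genes are not independent replicates.

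The last comparison set the control embryos of ED14.5 against those of ED7.5. Genes higher at ED14.5 included the embryonic globin Hbb-y (by 9.32), the erythroid membrane protein Rhag (by 9.29, at least 89.2-fold), Alb (by 9.08, at least 233-fold), the glucuronosyltransferase Ugt2b34 (by 8.72, at least 47-fold) and the fibrinogen chain Fgg (by 8.49). Hbb-y and Fgg were above background on 1 of 4 ED7.5 arrays, so their sizes are not exact. Among genes that were lower, Prl8a2 fell by 10.72 (at least 146-fold), Tdo2, a tryptophan dioxygenase, by 10.38 (at least 125-fold), Prl3c1 by 10.01 (at least 85-fold), Dmkn by 9.21 (at least 48.1-fold) and Erv3 by 8.94 (at least 68.3-fold). The adjusted p of these 10 genes was at most 1.01e-06. In all, 10121 genes passed, 5000 higher and 5121 lower, and the groups did not overlap in 9627 (49.4%, where chance gives 2.86%).

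Of 24 lists between the ages, 10 passed. Hepatocyte genes rose by a median of 6.94 (20 of 20 above 0, adjusted p = 0.0231 with an estimated correlation), with Fgb up by 7.47 (at least 77.7-fold), Vtn by 7.15 (2 of 4 ED7.5 arrays above background) and Trf by 6.01. Primitive erythroid genes rose by 5.41 (11 of 12 above 0, adjusted p = 0.0262 with an estimated correlation), with the transcription factors Nfe2 and Tal1 up by 6.22 (at least 15.4-fold) and 4.60 (1 of 4 ED7.5 arrays above background) and the haem enzyme Alas2 by 5.40. Decidua genes fell by a median of 5.53 (19 of 21 below 0, adjusted p = 0.00642 with an estimated correlation), with the angiopoietin Angpt2 falling by 6.11. These 3 held with an estimated correlation.

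The other 7 lists between the ages passed with the preset correlation and not with the estimated one. Visceral endoderm genes rose by a median of 5.21 (camera adjusted p = 0.000523, adjusted p = 0.371 with an estimated correlation). The members Afp, Apoa1, Apob, Ttr, Rbp4, Hnf4a, Fgb, Fga and Trf also belong to the hepatocyte list. The rise is therefore not separate from that of the hepatocyte genes. Imprinted genes rose by 1.37 (camera adjusted p = 0.000442, adjusted p = 0.129 with an estimated correlation), with Dlk1 up by 5.69 and Usp29 by 4.85 (at least 3.16-fold), and ribosomal protein genes by 0.35 (camera adjusted p = 0.00209, adjusted p = 0.687 with an estimated correlation). Parietal endoderm genes fell by a median of 2.35 (camera adjusted p = 1.02e-05, adjusted p = 0.097 with an estimated correlation), with the thrombin receptor Thbd falling by 4.07 (at least 12-fold). Extraembryonic ectoderm genes fell by 0.93 (camera adjusted p = 0.000158, adjusted p = 0.209 with an estimated correlation), with Eomes falling by 4.80 (at least 2.82-fold) and the placental cadherin Cdh3 by 4.77. Trophoblast giant cell genes fell by 2.73 (camera adjusted p = 0.00159, adjusted p = 0.298 with an estimated correlation), with Prl7a1 falling by 4.40 (at least 1.56-fold), and mesoderm genes by 0.91 (camera adjusted p = 0.0174, adjusted p = 0.169 with an estimated correlation), with Gata2 falling by 3.45. The giant cell and mesoderm lists also lost their call without the dimmest genes (adjusted p = 0.0846 for both).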

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

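Chosen only after the results were seen were the tests of tissue of origin on the embryo arrays, the tests that split the arrays for the gene counts of the SL comparisons, and the naming of Chordc1.

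High Cirbp with low Egr1 and Chordc1 in ED14.5 SL embryos was weighed first, Chordc1, a heat shock protein partner, at −0.86 (SE 0.121, adjusted p = 0.0611). Unequal numbers of male embryos and array quality are argued against. Eif2s3y was above background on 2 of 4 control and 1 of 4 SL arrays. In Cirbp all 4 SL arrays lay above all 4 control arrays. The separation of exon from intron control probes was 0.914 in control and 0.915 in SL arrays (exact permutation p = 0.886). Cirbp kept a change of 1.78 (SE 0.115) with the Y score as covariate and 1.79 (SE 0.109) with the separation. As the Y score did not separate the arms either (exact permutation p = 0.943), these kept changes add little. A lower body temperature or longer cooling before freezing is a candidate explanation: Rbm3, the other classical cold-inducible RNA-binding protein, was higher by 0.379 (SE 0.0889, adjusted p = 0.171), and a list of heat shock genes was lower by a median of −0.135, with 13 of 15 members below 0 (exact permutation p = 0.0286). In the liver the same list differed by −0.241 (13 of 15 below 0, exact permutation p = 0.0571) while Rbm3 differed by 0.027 and Cirbp by 0.20 (adjusted p = 0.974 and 0.763), so a low list is not particular to high Cirbp and Rbm3, and in that list the value of Hsph1 had been seen before and 4 members (Hspa1a, Hspa1b, Hsph1, Dnajb1) also belong to the stress response list. Whether such a temperature difference would arise in the animals or at collection cannot be read from these arrays, and an effect of the grandfather's obesity on these genes stays open and was not tested.

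Markers of 1 tissue far above those of the others on the embryo arrays were weighed next. Probes that do not work are argued against for 2 lists: the visceral endoderm genes, low at ED7.5, reached 10 log2 at ED14.5, and the genes of extracellular matrix, at 8.1 log2 at ED14.5, reached 10.3 log2 at ED7.5 (medians over the 8 arrays of the median of the list on each). Many visceral endoderm genes are also in the hepatocyte list, so their level at ED14.5 speaks for the probes and not for the tissue. The epiblast, neuron, skeletal muscle and cartilage lists stood at a mean percentile of 35.9 or lower in the control group of every age, so for them failed probes stay open. Whether maternal decidua makes up most of the RNA at ED7.5 stays open, though both signs set for it were met. Its markers led those of epiblast and visceral endoderm by at least 46.6 percentile points on every array, and the Y-linked Eif2s3y was above background on 0 of 8 arrays. Ranks do not measure shares, so this test could give no verdict for a majority. The same decidua probes stood at a mean percentile of 98.1 in ED7.5 control, 39.7 in ED14.5 control and 46.7 in liver control. Decidua transcripts were thus abundant at ED7.5, and their high rank is not a fixed property of the probes. A large share of fetal liver at ED14.5 stays open as well, since ranks of lists with different probes give no share of the RNA. There neurons, skeletal muscle and cartilage stood at percentile 38.4 or lower and the hepatocyte and definitive erythroid lists at 98.6 or higher on every array. On the same probes, ED14.5 control stood near liver control for neurons (22.1 against 17.9), skeletal muscle (33.4 against 28.4) and cartilage (35.9 against 33.4). Hepatocyte genes stood at 99.6 against 99.9, and definitive erythroid genes higher, at 99 against 82.6. The SL changes at ED14.5 therefore cannot be taken to stand for all tissues of the embryo.

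High Gdpd3 in ED7.5 SL samples was weighed last. A change of the whole chromosome region around the gene is argued against by its 6 nearest measured neighbours (Slx1b, Bola2, Coro1a, Ypel3, Tbx6 and Ppp4c), with a median change of −0.122 and a highest of 0.203. A larger share of epithelium is argued against by a median change of −0.197 in the epithelium list (exact permutation p = 0.6). Array quality is argued against, as the separation of control probes in SL (0.932 to 0.939) lay within the range in control (0.867 to 0.957). With the separation as covariate the change was 4.07 (SE 0.246). Chance could not be excluded, as 3 of the 35 splits of the 8 arrays called at least 1 gene, with 2 as the highest of the other splits. Decidua markers stood at a mean percentile of 98.1 on the control and 98.4 on the SL arrays of this age. Whether the Gdpd3 signal came from maternal or embryonic tissue therefore cannot be told. An effect of the grandfather's obesity stays open and was not tested.

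Other splits of the arrays were counted for every comparison. For genes, the real split called the most at ED14.5 (1 of 35 splits as large, 10 genes against at most 1 in another split). The same held between the ages (1 of 35, 10121 against at most 0). A share of 1 of 35 is the smallest that these splits allow, and the ED14.5 count was chosen after its result was seen. Litters or grandfathers shared within a group could not be told from the groups by such splits. In the liver 0 genes passed by limma, with 1543 at an unadjusted p below 0.05, so 35 of 35 splits count as large whatever they call (highest other 1), and this decides nothing. For lists chance could not be excluded in the SL comparisons: 30 of 35 splits were as large at ED7.5 (1 list, highest other 9), 4 of 35 at ED14.5 (6, highest other 8) and 4 of 35 in the liver (8, highest other 14), where 2 of the 3 other splits at each of these 2 ages kept 3 of the 4 arrays of a group together. Between the ages 6 of 35 splits called as many lists (10, highest other 12), but the other 5 each kept 3 of the 4 arrays of an age together and so carry part of the age difference, and this count does not test it. For differences of the SL effect, the real grouping called the most between ED14.5 and ED7.5 (1 of 100 regroupings as large, 15 genes, highest other 8). Between liver and ED7.5 chance could not be excluded (16 of 100, 1 gene, highest other 4). Between liver and ED14.5 the share was under 0.05 (3 of 100, 5 genes). Another regrouping gave 26 genes, several times the real count, for a reason that was not tested, and these 5 genes stay open.

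Single arrays stood far from the other 3 of their group in 12 of 281 groups tested, where chance gives about 1 in 20. The gap divided by the range of the group was 0.923 for Btc in ED7.5 control (replicate 1, low) and 0.832 for Ugt2b34 there (replicate 2, high). In ED14.5 control it was 0.85 for Glo1 (replicate 2, high), 0.897 for Hbb-y (replicate 1, low), 0.864 for Igfbp1 (replicate 4, high) and 0.886 for the separation of exon from intron control probes (replicate 1, low). In ED14.5 SL it was 0.955 for Akr1c19 (replicate 2, high), 0.879 for Pdk4 (replicate 3, high), 0.831 for Pex11a (replicate 1, low) and 0.884 for the mean of the cholesterol genes (replicate 3, high). In the liver it was 0.917 for Irf7 in control (replicate 4, low) and 0.869 for Nr1h3 in SL (replicate 1, low).

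Named genes whose SL change differed between ages, by the interaction test, included stress and metabolic genes. From ED7.5 to ED14.5 the change differed by 2.07 for Cirbp (adjusted p = 1.13e-05), −4.23 for Gdpd3 (0.000359), 1.18 for Sat2 (0.00985), 1.40 for Pdk4 (0.0107), −1.23 for Hsph1 (0.0134), −1.46 for Egr1 (0.0151) and 1.07 for Btc (0.0382). Btc was above background on 1 of 8 ED7.5 and 0 of 8 ED14.5 arrays, so its difference cannot be placed. For the liver the difference from ED7.5 was −3.30 for Gdpd3 (adjusted p = 0.0357), and that from ED14.5 was −1.59 for Cirbp (0.00115) and −2.21 for Slc22a28 (0.0288). The sizes for Gdpd3, above background on 1 of 8 arrays at ED14.5 and in the liver, and for Slc22a28, on 0 of 8 at ED14.5, rest in part on values below background and are not exact.

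Lists whose SL change differed between ages are given as the median over the members of each gene's difference, with camera's adjusted p and then the adjusted p with an estimated correlation. Only lists that camera called in an SL comparison were tested here, and the adjustment covered these lists alone. They were chosen for their change in these same data, so the p-values are not independent of that choice. From ED7.5 to ED14.5 the unfolded protein response differed by −0.26 (9.02e-07, and 0.026 with an estimated correlation), cholesterol synthesis by −0.24 (1.06e-05 and 0.194), fatty acid synthesis by −0.20 (0.00114 and 0.194), PPARα targets by 0.13 (0.00114 and 0.194), NRF2 genes by 0.13 (0.0124 and 0.301) and granulocyte genes by 0.34 (0.0124 and 0.32). From ED7.5 to liver the differences were −0.30 for cholesterol synthesis (6.49e-09 and 0.122), −0.19 for ribosomal proteins (9.33e-06 and 0.356), −0.28 for the cell cycle (9.41e-06 and 0.423), −0.20 for the unfolded protein response (6e-05 and 0.122) and −0.18 for fatty acid synthesis (0.000155 and 0.13). They were 0.31 for granulocytes (0.00371 and 0.344), −0.31 for definitive erythroid cells (0.00751 and 0.453) and −0.25 for the interferon response (0.0393 and 0.423). From ED14.5 to liver they were −0.18 for PPARα targets (3.8e-05 and 0.218), −0.35 for the interferon response (0.000541 and 0.344), −0.22 for the cell cycle (0.000541 and 0.612), −0.16 for ribosomal proteins (0.000689 and 0.612), −0.30 for definitive erythroid cells (0.0155 and 0.612) and −0.079 for NRF2 genes (0.0204 and 0.592). Of these, the unfolded protein response between ED7.5 and ED14.5 is the difference below 0.05 with an estimated correlation. That value was adjusted over the chosen lists alone, so it does not establish a difference over all lists.

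Among the 2634 probe sets that name no gene here, 984 passed between the ages of the control embryos, with 547 higher and 437 lower at ED14.5.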

How the results depend on the processing

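Chosen only after the data were seen were the tests with the separation of control probes or the epiblast genes as covariate, and the liver lists without control replicate 3 and SL replicate 1 (8 lists).

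Between the ages of the control embryos all 24 named genes kept their direction and call under every alternative run, with 8493 to 11342 genes past the threshold, and 9457 to 9916 without single arrays. Named genes in the SL comparisons reversed under 0 of the alternatives run, where a reversal was counted only if the gene passed in the main fit or in that alternative. Changes of sign in genes that passed in neither were not counted. At ED14.5 Cirbp was lost under the replicate block alone (adjusted p = 0.0513, range over its alternatives 4.28e-09 to 0.0513), while Gdpd3 passed in 15 of its 21 alternatives (adjusted p from 7.2e-06 to 0.0964), Zc3h6 in 15 of 20, Rap1gap in 11, Egr1 in 10 and Glo1 in 8 of 20. For each of these genes the counts include the adjusted p under 0.10 and the minimum change of 0.5. Both reuse the p-values of the main fit and could not fail for a called gene here. After subtracting group means, same-numbered SL and control samples correlated across genes at −0.165 to 0.116, and the best match was their own number for 4 of 12, 3 of these in the liver, so pairing is not shown at the embryo ages and stays open in the liver. Cholesterol synthesis passed in 12 of 15 alternatives at ED14.5 (to 0.557) and 13 of 16 in the liver (to 0.45), interferon genes in 11 of 16 (to 0.596) and Kupffer genes in 12 of 16 (to 0.45). Genes below background in both arms have changes that signal over background cannot place.

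Gene counts at ED7.5 were 3 with the trend and robust prior, 12 in the fit of all 24 arrays, 0 with the Y score as covariate, 2 with the epiblast covariate and 0 to 2 without single arrays (0 without control replicate 1 or any SL replicate, 2 without control replicate 3 or 4), against 1. At ED14.5 they were 283, 79 and 2 with the trend, the 24-array fit and the Y score, 0 with the replicate block, 98 without the dimmest 33% of genes, where fewer genes are tested, 98 at an adjusted p under 0.10, 4 with the control probe covariate and 1 to 5 without single arrays, where samples are fewer, against 10. In the liver they were 5 in the 24-array fit, by limma, and otherwise 0. List counts at ED7.5 were 0 with an estimated correlation, 0 with fry, 0 by permutation, 2 without the dimmest genes and 0 to 4 without single arrays (0 without control replicate 2, SL replicate 2 or 4, 3 without SL replicate 1, 4 without SL replicate 3, 2 without control replicate 4). At ED14.5 they were 0, 0 and 0 by these methods, 3 with the Y score and 3 to 7 without single arrays (3 without control replicate 3). In the liver they were 0, 0 and 0, and between the ages 3 with an estimated correlation, 18 with fry and 18 by permutation. With 31 or 33 lists the smallest exact permutation p, 0.0286, passes only if most lists reach it. Pancreas genes in the liver reversed with the Y score (adjusted p = 0.0015) and the control probe covariate (0.0333), from 0.765, and epithelial genes of kidney, lung and gut between the ages with fry (0.0061) and permutation (0.0381), from 0.859. Differences of the SL effect between ED14.5 and ED7.5 numbered 35 with the trend, 46 with array weights, 5 with the block, 28 without the dimmest genes and 35 at an adjusted p under 0.10, against 15. Those between liver and ED7.5 numbered 0 with array weights, 0 with the block and 0 with the Y score, against 1. Those between liver and ED14.5 numbered 28 with the trend, 3 with the block, 18 without the dimmest genes and 32 at an adjusted p under 0.10, against 5. Except where fewer genes or samples are named, the cause was not tested.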

Other observations

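The time-of-day and heat shock tests were chosen after the changes that prompted them were seen, and single clock genes were picked from a fixed list after their values were seen.

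Stress and immediate early genes at ED14.5 went both ways in SL embryos. The list of 22 glucocorticoid and stress response genes did not move as a whole (camera adjusted p = 0.724), with a median change of 0.06 and a mean of −0.01 that differ in sign. Adjusted over the list alone, 5 of its members rose and 4 fell. Those that fell were Egr1 and the immediate early genes Ier2 by 0.64 (adjusted p = 0.0184) and Junb by 0.63 (adjusted p = 0.0193), and the chaperone Hsph1 by 0.98 (SE 0.151, adjusted p = 0.00114). Among those that rose were Per1, a clock gene that glucocorticoids also induce, by 0.88 (SE 0.152, adjusted p = 0.00182), and Ier3 by 0.70 (adjusted p = 0.0184).

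Lists of other cell types and responses did not pass at ED14.5. Interferon response genes had a median change of 0.12 (camera adjusted p = 0.273), primitive erythroid genes −0.13 (adjusted p = 0.0993), placental genes −0.04 (adjusted p = 0.623), imprinted genes −0.09 (adjusted p = 0.215) and the epithelial genes of kidney, lung and gut 0.15 (adjusted p = 0.198). At ED7.5 the genes of extracellular matrix had a median change of 0.12 and those of oxidative phosphorylation 0.07 (adjusted p = 0.138 for both), extraembryonic ectoderm −0.10 (adjusted p = 0.18) and trophoblast giant cells −0.37 (adjusted p = 0.611). Heat shock genes had a median change of 0.09 at ED7.5 (exact permutation p = 0.229) and of −0.24 in the liver (exact permutation p = 0.0571, 13 of 15 below 0). The Y score did not separate the arms at ED7.5 (exact permutation p = 1) or ED14.5 (exact permutation p = 0.943), and Eif2s3y was above background on 2 of 4 control and 1 of 4 SL arrays at ED14.5 and on all 8 liver arrays. Of the probe sets without a gene name, 2 fell at ED14.5, and 0 passed at ED7.5 or in the liver by limma.

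High Per1, Pdk4 and Igfbp1 in ED14.5 SL embryos may reflect a different time of day at collection, which was tested on other clock genes. The mean of 9 clock output genes minus that of 5 genes in phase with Bmal1 differed by −0.196 log2 between SL and control (exact permutation p = 0.0571), with an SD of 0.198 in control and 0.0618 in SL. Per2 differed by −0.49 (SE 0.115), Dbp by −0.26, Nr1d2 by 0.35 and Nfil3 by 0.55 (SE 0.146, adjusted p = 0.223). With 4 arrays per arm and members on both sides of 0, this hypothesis could neither be kept nor ruled out.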
